A study of Mus musculus with 8 samples.

How the data were processed

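m6A sequencing was done on mouse embryonic stem cells with a doxycycline-inducible knockdown of Setd2, per the labels. There were 8 libraries: IP and input, with and without Dox, in 2 replicates each. The cells grew with 1 µM PD0325901 (a MEK inhibitor), 3 µM CHIR99021 (a GSK3 inhibitor) and 1000 U/ml LIF, and Dox cells received 1 µg/ml for 4 days. Messenger RNA was purified and fragmented by sonication, IP libraries were enriched with an m6A antibody, and all libraries were made with a stranded kit, per the labels' protocols. The submitters' processing notes name FastQC 0.11.5, TopHat2 2.1.1 and the build mm10. The peak tables come from exomePeak, per the names of the deposited tables, and its version, settings and gene annotation are not given in the sources used here. Nothing in the labels says whether the replicates came from separate cultures.

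The authors deposited 1 peak table and 1 shorter peak list per condition, and the labels tie each of them to all 4 libraries of that condition, so both replicates are pooled in every value. The fold enrichment is a ratio of IP over input per peak, per the file headers, and how IP and input were scaled is not given in the sources used here. The deposited tables hold the log10 of each peak's p and of its FDR in 2 columns, per the file headers. The p-value of each peak is a column of its own in the deposited tables, headed score, and in the lists. Its log10 was checked to equal the log10 p given. The shorter list of each condition was checked to be exactly the table's peaks with a p of at most 1e-05 and a fold of at least 2. No value per library was analysed here, so sequencing depth is unknown, no replicate spread can be given and no test between the conditions was made. Percentages have exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only and take peaks as independent.

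A control peak counted as shared when it had at least 1 exonic nucleotide in common with a Dox peak on the same strand, taken over the exonic blocks of both peaks with bedtools 2.31.1, and the reverse. Genes were counted by the Ensembl identifiers of the deposited tables. The tables and the reference share no identifiers, so gene symbols were assigned by location. An identifier received the symbol of the protein-coding RefSeq gene (GRCm38.p6, the assembly of mm10) whose interval held most of its peak midpoints, at least 50% of them and without a tie. Where several identifiers fell in 1 gene, the one with most peaks was kept. This named 10444 of the 13110 identifiers (79.7%), which carry 88.6% of control and 89.0% of Dox peaks. Overlapping genes on opposite strands and clustered gene families can be misnamed by this rule, and values of zinc finger, Usp17 and ribosomal protein genes, which have close copies, are uncertain for that reason too. Coordinates are 1-based mm10 positions.

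Peaks were placed along RefSeq gene intervals of at least 3000 nt by the midpoint of their exonic length: within 500 nt of the 5' end, within 1000 nt of the 3' end, or between. This replaced the distribution over untranslated and coding regions planned before the data were examined, which needs exon annotation, and was chosen after the data were seen. The planned search for the m6A consensus motif needs a genome sequence, which was not used here.

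For each of 11 gene lists, the percentage of the members' peaks without an overlapping peak in the other list was ranked among 10000 random lists of named genes with as many members, matched on classes of peak number and quintiles of the highest fold in the list that holds the peaks. The lists, the rule for the genes named and the alternatives not said to be added later were written before the data were examined. Tests of explanations in the closing section were written later, once the patterns were known. The rule took Setd2 and all m6A genes. From every list it took up to 4 members with peaks in both conditions, in control only and in Dox only, by highest fold. It added 10 genes per condition with the highest fold among those with a peak at a log10 FDR of -5 or less and no peak in the other condition, and 5 genes whose top control peak overlaps a Dox peak. Predicted genes with Gm or Rik names were left out of the last 25. Some genes that the rule takes are not reported here. Genes outside the rule are said to have been named after their values were seen.

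Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9. On simulated peaks, 300 per list, the overlap calls had 0 errors against counting nucleotide by nucleotide. In a simulation over 11650 genes with 200 genes given doubled loss of control peaks, all 10 lists of 20 such genes lay above the 97.5th percentile, and 4 of 100 lists of unchanged genes lay outside the 2.5th to 97.5th. The simulation gave all unchanged genes the same rate of loss, whereas loss in the real lists depended on the log10 FDR. It therefore does not show how often unchanged real lists fall outside these bounds. The alternatives were peaks at a log10 FDR of -5 or less, peaks with a fold of at least 4, the authors' shorter lists, overlap of at least 50% of the shorter peak, strand ignored, and genomic spans in place of exonic blocks. Others were a filter on the query list alone, equal numbers of peaks, and at least 2 peaks per gene. All alternatives for peak positions were added after the data were seen, among them windows of 200 and 1000 nt at the 5' end.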

Results

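N6-methyladenosine (m6A), a methyl mark on adenosines of messenger RNA, was mapped in mouse embryonic stem cells with and without knockdown of Setd2. SETD2 is the enzyme that trimethylates lysine 36 of histone H3 (H3K36me3) along transcribed genes. The cells carried a knockdown construct switched on by doxycycline (Dox) and grew as spheres without feeder cells, in serum-free 2i medium with LIF, which blocks MEK and GSK3 and holds the cells in a naive pluripotent state. Dox was given at 1 µg/ml for 4 days, and untreated cells were the control. No library came from Dox-treated cells without the knockdown construct, so an effect of Dox itself cannot be told apart from the knockdown. The 8 libraries formed 4 groups of 2 replicates: RNA pulled down with an m6A antibody (IP) and input RNA, each from control and from Dox cells. The values analysed are 1 list of m6A peaks per condition, each called by the authors on its replicates together. The number of reads behind each library and each peak is unknown, and no replicate spread can be had, so no difference between the conditions was tested. Percentages below carry exact (Clopper-Pearson) 95% intervals that cover counting error only.

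Setd2, the targeted gene, carried m6A peaks in both conditions, with 10 peaks in the control list and 6 in the Dox list. The gene (ENSMUSG00000044791.16) lies on the plus strand of chromosome 9 from 110532500 to 110618633 (mm10). Of its control peaks, 5 had no overlapping Dox peak, while 1 of its Dox peaks had no overlapping control peak. Those 5 were weak, with log10 FDRs from -1.53 to -4.54, and 40.4% of all control peaks above -5 had no Dox peak. Its control peak of highest fold enrichment spanned 110573909 to 110574239 on chromosome 9, with an IP over input fold of 10.2 and a log10 FDR of -54.7. The Dox peak of highest fold overlapped it and began at 110573939, with a fold of 6.51 and a log10 FDR of -6.96. Folds and FDRs are the authors' own values for single peaks. A peak list does not measure transcript level, so the extent of the knockdown cannot be read from it.

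**Figure D1:**
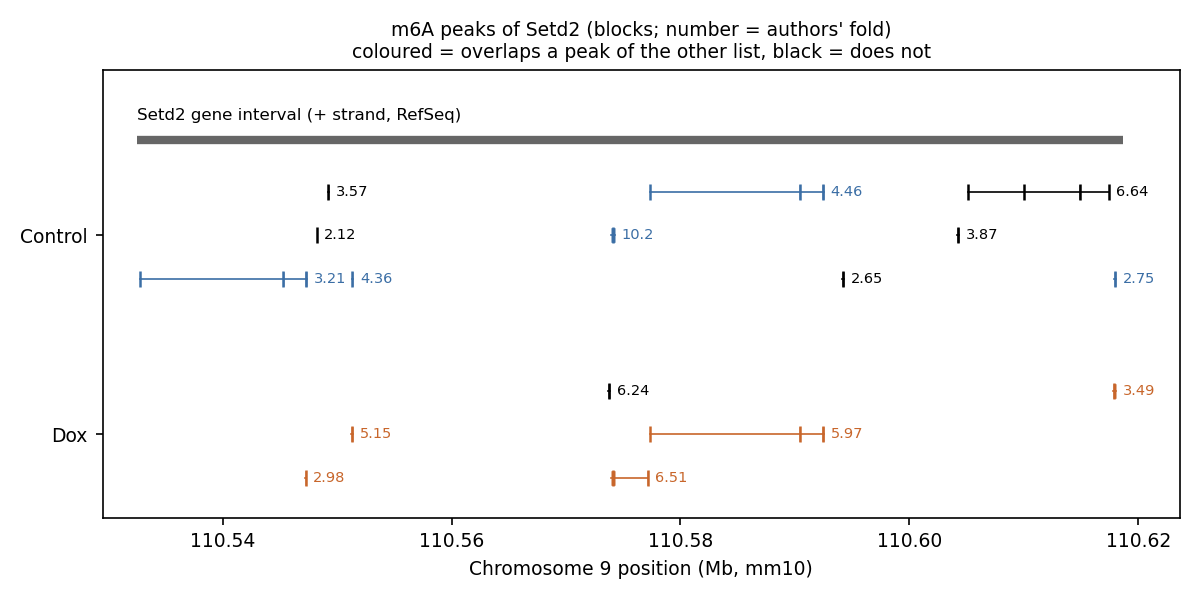
m6A peaks of Setd2 in the control list (upper rows) and the Dox list (lower rows), by position on chromosome 9 in Mb (mm10). Ticks are the exonic blocks of a peak (short blocks are drawn at a minimum width), thin lines join blocks across introns, the number is the authors' fold, and the 5 control peaks and 1 Dox peak drawn in black overlap no peak of the other list.

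The first comparison asks whether Setd2 knockdown changed how many m6A peaks the cells carried. Most genes with m6A peaks had them in both conditions, and peaks of high fold were far fewer in the Dox list. The control list held 25815 peaks on 11650 genes and the Dox list 27612 peaks on 11941 genes. With a fold of at least 4, the control list held 14928 peaks and the Dox list 11394. At a fold of 8 or more the numbers were 6925 and 2595, and at 24 or more 744 and 54. The median fold was 4.62 in the control list (quartiles 2.88 and 8.34) and 3.51 in the Dox list (quartiles 2.44 and 5.29). The median exonic width was 211 nt for control peaks and 240 nt for Dox peaks. The sign of the difference in total number depended on the threshold: the authors' stricter lists (p of at most 1e-05 and fold of at least 2) held 16914 control peaks and 15500 Dox peaks. Folds of separately called lists depend on read depth and pull-down, so these numbers describe the lists. High folds of weak peaks are also coarse, as found after the data were seen. At log10 FDRs above -8 and folds of 8 to 40, 77.3% of control folds were whole multiples of 1.23, within rounding (6.43% by chance). Of such Dox folds, 80.4% were whole multiples of 1.0845 (7.50% by chance).

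**Figure D2:**
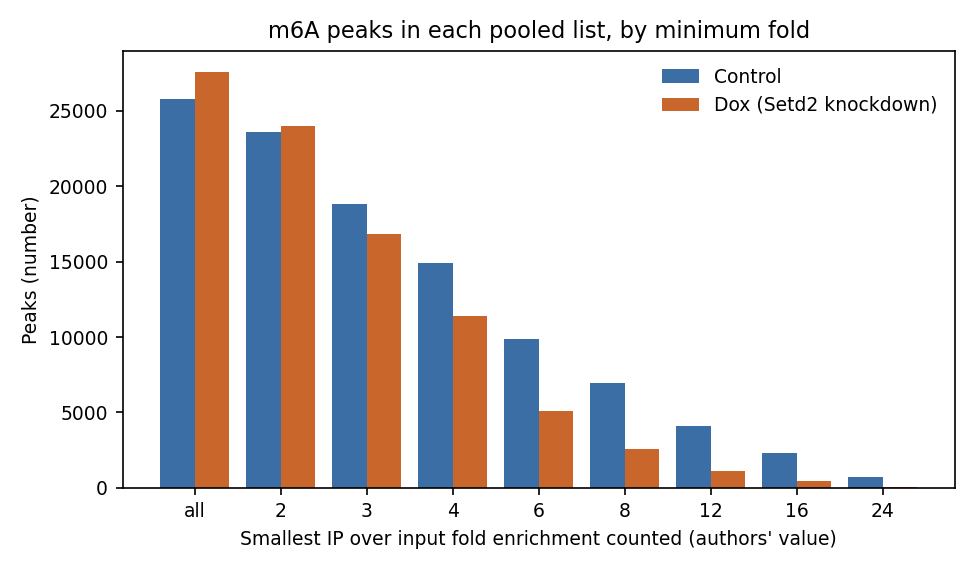
Number of m6A peaks in each pooled list (vertical axis) with at least the authors' fold enrichment shown on the horizontal axis, control in blue and Dox in orange. The Dox list is longer over all peaks (27612 against 25815) and shorter from a fold of 3 upwards (16822 against 18832), down to 54 against 744 at a fold of 24.

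The second comparison asks which m6A peaks of control cells were also called after knockdown. Most were: 80.7% of control peaks shared at least 1 exonic nucleotide on the same strand with a Dox peak. Of the 25815 control peaks, 4983 (19.3%, interval 18.8% to 19.8%) had no overlapping Dox peak. In the other direction 8024 of the 27612 Dox peaks (29.1%, 28.5% to 29.6%) had no overlapping control peak. With both lists at a fold of at least 4 this order turned, to 45.7% of control and 31.6% of Dox peaks. It also turned in the authors' stricter lists (24% and 22.3%), but not at a log10 FDR of -5 or less (21.0% and 22.3%). Well supported peaks were shared far more often. At a log10 FDR of -20 or less, 1.36% of control peaks (1.13% to 1.63%) and 2.80% of Dox peaks (2.45% to 3.20%) lacked a counterpart. Above a log10 FDR of -5 the shares were 40.4% and 52.1%. With a control list limited to a log10 FDR of -5 or less and the full Dox list, 7.56% lacked a counterpart (7.16% to 7.97%), and the reverse gave 11.6% (11.1% to 12.1%). Dox peaks that spanned at least 2 control peaks numbered 2258, and control peaks that spanned at least 2 Dox peaks numbered 1272.

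At the level of genes, 10481 carried peaks in both conditions, 1169 in control only and 1460 in Dox only. In the authors' stricter lists the order turned, with 1422 genes in control only and 974 in Dox only. Of the genes with a control peak at a log10 FDR of -5 or less, 274 had no Dox peak at all, and 292 genes with such a Dox peak had no control peak. Among the control genes without a Dox peak, 10 were named by their highest fold. Olig3, a neural transcription factor, came first with a fold of 54.1 (chromosome 10, 19357390 to 19357598). It was followed by the placental transcription factor Gcm1 (49.2; chromosome 9, 78065385 to 78065624) and the imprinted gene Peg12 (48.0; chromosome 7, 62464180 to 62464510). Next came Usp17la, a deubiquitinase gene (40.6), the sphingosine phosphate phosphatase gene Sgpp1 (40.6) and Uty, a histone demethylase gene of the Y chromosome (39.4). The remaining 4 were Jchain (35.7), the mesoderm factor T (33.2), the bone factor Runx2 (33.2) and Prkag3 (32.0). Each of these 10 genes had a single control peak, with log10 FDRs from -13.0 for Olig3 to -7.01 for Prkag3. All 10 folds are whole multiples of 1.23 within rounding, so the ranking is by coarse values.

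Genes with Dox peaks and no control peak were ranked in the same way. Atp2b2, which encodes a plasma membrane calcium pump, had 5 Dox peaks and a highest fold of 27.1 (chromosome 6, 113748354 to 113748594). The p38 kinase gene Mapk12 followed at 17.4 (chromosome 15, 89130675 to 89130885). Zswim5 and Tvp23a both reached 9.76. The sulfotransferase gene Sult2a1 had a fold of 8.32 and the glycosyltransferase gene Galnt9 one of 8.13. Irak4, a kinase of innate immune signalling, had a fold of 7.05, Alg8 one of 6.20, Zfp992 one of 6.10 and Ttc9 one of 5.97. Their log10 FDRs lay between -8.49 for Zswim5 and -5.01 for Tvp23a, so these are among the weaker peaks that pass the limit of -5. The first 4 folds are whole multiples of the Dox step of 1.0845 within rounding. Galnt9, Irak4 and Ttc9 lay at 7.5, 6.5 and 5.5 steps and Sult2a1 at 7.67, so their folds may be coarse as well. Alg8 and Zfp992 lay at 5.72 and 5.62 steps.

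Among genes whose top control peak was also called in Dox, Ano9, a gene of the anoctamin family, came first. Its control peak had the highest fold of the list (133) and overlapped the gene's only Dox peak (4.23 within the Dox list). Both peaks ended at 141117806 on chromosome 7. Basp1 (108), Arpc5 (108), Crebzf (98.4) and Ybx1 (96.0) followed in the control list, and the top peak of each overlapped a Dox peak. Within the Dox list the top peaks of these genes had folds of 10.8, 14.6, 7.71 and 11.4. All genes in this paragraph, Ano9 included, were chosen for their high control folds. Lower folds in the Dox list may follow from that choice alone and do not show a drop in m6A. Whether their control folds are coarse, like those of the control genes without a Dox peak, was not tested. At Arpc5 the control and Dox peaks had the same bounds, 152766542 to 152768592 on chromosome 1.

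The third comparison asks where along genes the peaks without a counterpart lie, since H3K36me3 marks gene bodies more than their starts. Peaks centred near gene 5' ends were fewer in the Dox list. Peaks further along the gene were more numerous in the full tables, but not under every filter. Within 500 nt of the 5' end of the gene there were 2856 control peaks, 12.9% of those placed, and 1834 Dox peaks, 7.69%. Between the ends the numbers were 16157 and 18321, and within 1000 nt of the 3' end 2948 and 3546. These 2 parts together held 19105 control and 21867 Dox peaks, but 10364 and 8859 at a fold of at least 4 and 12635 and 12545 in the authors' stricter lists. Of the control 5' end peaks 38.2% (36.4% to 40.0%) had no overlapping Dox peak, against 16.1% (15.5% to 16.6%) between the ends and 10.8% (9.66% to 11.9%) at the 3' end. Under other filters and windows this 5' end share lay between 21.2% and 64.2% and stayed above that between the ends. Among Dox peaks the order by position was the opposite: 14.6% (13.0% to 16.3%) at the 5' end, 30.1% (29.5% to 30.8%) between and 31.2% (29.7% to 32.8%) at the 3' end lacked a control peak. The order among control peaks is the reverse of a loss of whole peaks that follows H3K36me3, which was not measured here. A peak that weakens but is still called counts as shared, so these shares cannot show a partial loss in gene bodies. Lower coverage of 5' ends in the Dox libraries also stays open. The order therefore does not argue against a loss that follows H3K36me3. In all, 2791 genes had a 5' end peak in control, 1793 in Dox and 1473 in both. Placement was by peak midpoint, so a Dox peak that covers a control 5' end peak but reaches further along counts elsewhere. Btg2, named after its values were seen, had 2 control peaks, 1 at the 5' end, both with a counterpart. Its only Dox peak was centred elsewhere. Counts of 5' end peaks can therefore fall without loss of a peak. Positions are distances within RefSeq gene intervals, a measure chosen after the data were seen, because untranslated and coding parts were not analysed here.

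The excess at 5' ends was present among control peaks of matched strength. At log10 FDRs between -10 and -5, 46.4% of 5' end peaks (42.1% to 50.7%) lacked a Dox peak, against 14.2% (12.9% to 15.5%) between the ends and 10.4% (7.81% to 13.5%) at the 3' end. Between -50 and -20 the shares were 8.42% (5.90% to 11.6%), 1.62% (1.15% to 2.21%) and 0.849% (0.232% to 2.16%). Below -50 they did not differ beyond counting error, at 0.460%, 0.356% and 0.299%. Genes with at least 1 Dox peak held 322 control 5' end peaks at a log10 FDR of -5 or less without an overlapping Dox peak. The highest folds among them, named after their values were seen, belonged to Suds3, a subunit of the SIN3 corepressor complex (98.4; chromosome 5, 117113484 to 117116023), and Hs2st1, a heparan sulfate sulfotransferase gene (48.0). Commd7 and Rbm15b followed at 46.7 each, then the semaphorin receptor gene Nrp2 (45.5) and the G protein subunit gene Gnb1 (44.3). All 6 folds are whole multiples of the control step of 1.23, so they too are coarse. The Suds3 peak was centred 179 nt from the 5' end of a gene that had 6 peaks in either condition.

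**Figure D3:**
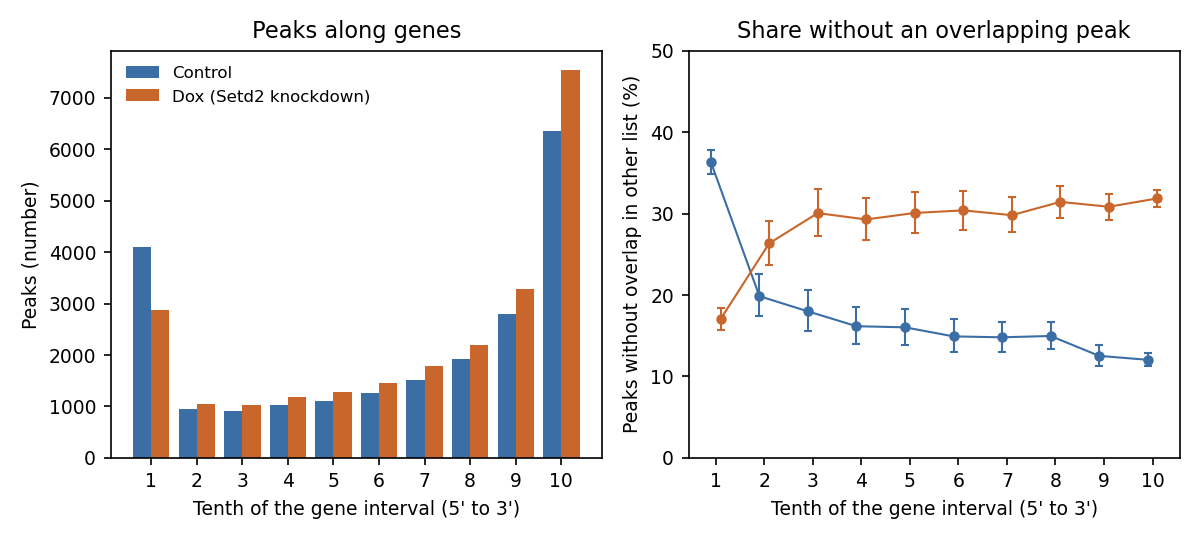
Number of peaks (left) and percentage without an overlapping peak in the other list (right) per interval of 10% of the gene from 5' to 3'. Peaks are placed by midpoint, control in blue and Dox in orange, with exact 95% intervals that cover counting error only. In the first interval control holds more peaks than Dox (4098 against 2883) and 36.3% of them lack a counterpart against 17.0%, while in the last interval the numbers are 6361 and 7541 and the shares 12% and 31.9%.

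The fourth comparison asks how gene groups relevant to naive stem cells and to the knockdown fared, using 11 lists fixed before the data were examined. For each list the share of peaks without a counterpart was ranked among 10000 random lists of the same size, matched on peak number and highest fold. Of the 22 shares (11 lists in both directions), 5 fell outside the 2.5th to 97.5th percentile, where 1.1 would be expected by chance. These percentiles describe the lists and are no test of the knockdown. Members named below are ranked by fold alone, and some high folds belong to weak peaks, whose folds are coarse. Examples are Cdk6 in control (17.2, log10 FDR -3.21) and Dusp4 in Dox (20.6, log10 FDR -4.25). Most depended on the matching: with random lists matched on the lowest log10 FDR, a choice made after the data were seen, 4 shares fell outside, and only 1 of them was among the former 5. Of those 5, 2 stayed outside with both lists limited to a log10 FDR of -5 or less and 1 at a fold of at least 4. A further 1 and 3 shares lay outside under these filters, and with overlap of at least 50% of the shorter peak all 5 stayed outside together with 2 others (Dox peaks of apoptosis genes, percentile 1.78, and of fibroblast markers, 2.46).

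**Figure D4:**
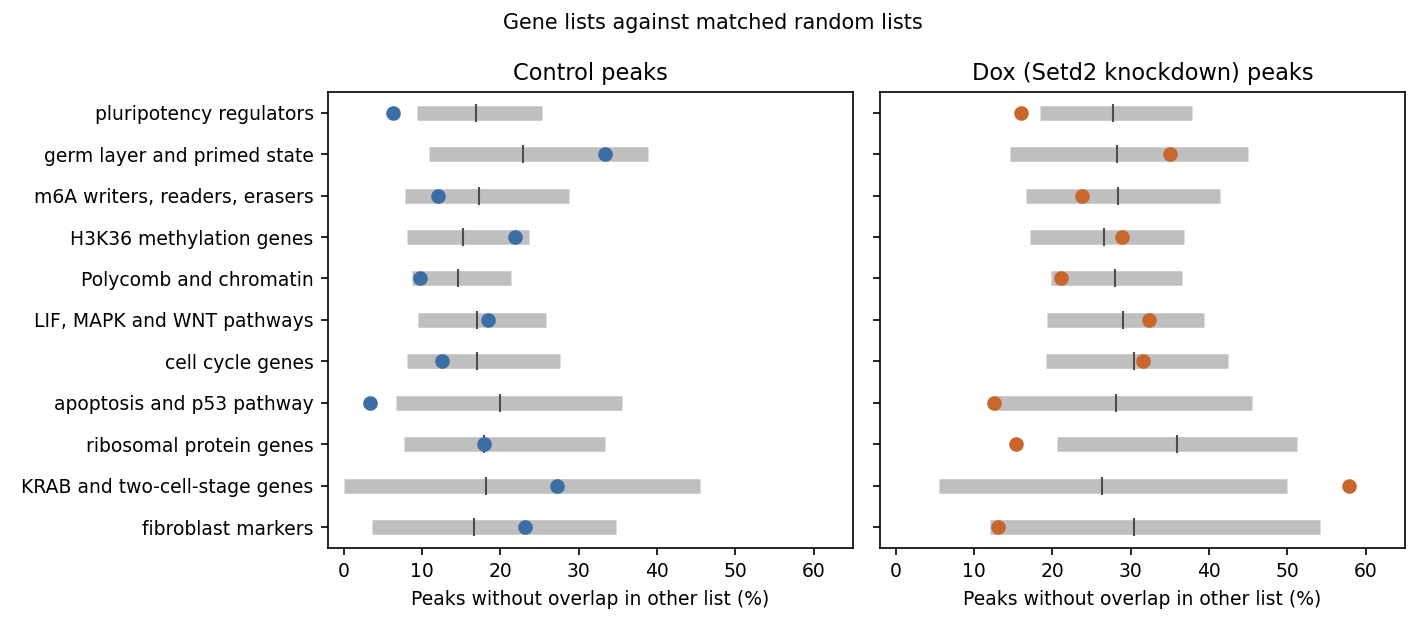
Percentage of each gene list's peaks without an overlapping peak in the other list (dots; control peaks left, Dox peaks right) beside matched random lists (grey bars, 2.5th to 97.5th percentile; ticks, median). Pluripotency regulators lie below their bars on both sides (6.25% and 16%), and KRAB and 2-cell-stage genes lie above theirs for Dox peaks (57.9%).

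In the full tables, pluripotency regulators retained nearly all of their control m6A peaks. Peaks in both conditions were found for 32 of the 34 members with a peak, and 6 of the list's 96 control peaks (6.25%, 2.33% to 13.1%) had no Dox peak. This share lay at percentile 0.185 of lists matched on fold and at 6.44 of lists matched on log10 FDR. It was 8.97% at a log10 FDR of -5 or less in both lists (percentile 1.95) and 31.4% at a fold of at least 4 (percentile 7.82). The orphan nuclear receptor gene Nr0b1 (control fold 34.7), the RNA-binding ubiquitin ligase gene Trim71 (33.2), Gbx2 (26.7) and Mybl2 (20.8) led the control list, and the top peak of each overlapped a Dox peak. The core factors Pou5f1, Sox2 and Nanog, named after their values were seen, had 2, 1 and 1 control peaks, each with an overlapping Dox peak. Prdm14, with 2 peaks of a highest fold of 2.16, and Tcl1, with 1 peak of 1.39, were found in Dox only. Of the 94 Dox peaks, 15 (16%) had no control peak, at percentile 0.67, at 21.4 with matching on log10 FDR, and at 49.8 among peaks at a log10 FDR of -5 or less (22.6%), but stayed outside the bounds at a fold of at least 4 (15% of 40 peaks, percentile 1.69).

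Regulators of germ layers and of the primed state, which naive cells express little, had the highest number of members with peaks in a single condition, though not the highest share. Over all identifiers 10481 of 13110 had peaks in both conditions, and among KRAB and 2-cell-stage genes 4 of 7 members with a peak did. Of the 23 germ layer and primed state members with a peak, 14 had peaks in both conditions, 6 in control only and 3 in Dox only. The control-only genes included T (33.2), the neural factor Pax6 (20.9), the endoderm factor Gata4 (17.2) and Sox3 (16), each with 1 peak. The log10 FDRs of these peaks were -7.69, -7.69, -3.21 and -2.9. The Dox-only genes were Bmp4 with 2 peaks (20.6), the mesendoderm factor Eomes with 2 (17.4) and Otx2, a factor of the primed state, with 3 (3.88). Their top peaks had log10 FDRs of -4.48, -3.92 and -17.9, so the high folds of Bmp4 and Eomes are those of weak peaks. Sox11 (64.0), Nes (25.5), Zic2 (19.7) and Pou3f1 (16) had control peaks that were also called in Dox. Of the list's 36 control peaks 12 lacked a counterpart (33.3%, 18.6% to 51%), at percentile 90.6 with matching on fold and 98.0 with matching on log10 FDR. Of its 40 Dox peaks 14 did (35.0%), at percentile 79.8.

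All 18 genes found among the writers, readers and erasers of m6A carried peaks in both conditions. They held 58 control peaks, 7 of them (12.1%, 4.99% to 23.3%) without a Dox peak, and 59 Dox peaks, 14 of them (23.7%, 13.6% to 36.6%) without a control peak. These shares lay at percentiles 16.2 and 22.7. Every control peak had a counterpart at the methyltransferase gene Mettl3 (3 peaks), at its complex partners Wtap (4), Virma (3) and Rbm15 (2) and at the demethylase gene Alkbh5 (2). The same held for the reader genes Ythdf1 (3), Ythdf2 (4), Ythdc1 (3), Igf2bp1 (4), Igf2bp2 (4), Hnrnpa2b1 (2) and Hnrnpc (1). Control peaks without a counterpart lay in Mettl14 (1 of 2), Zc3h13 (1 of 7), Rbm15b (1 of 4), Mettl16 (1 of 2), Fto (2 of 5) and Ythdf3 (1 of 3). The Rbm15b peak, at 106886801 to 106887010 on chromosome 9, had the highest control fold of the list (46.7), ahead of peaks of Zc3h13 (32.4), Ythdf2 (17.5) and Rbm15 (14.6).

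Genes that write, erase or read H3K36 methylation had peaks in both conditions in 20 of 23 members. Of their 96 control peaks 21 (21.9%, 14.1% to 31.5%) had no Dox peak, at percentile 94.0 with matching on fold and 98.4 with matching on log10 FDR. With matching on fold the share was 18.2% at a log10 FDR of -5 or less (percentile 72.4) and 31.7% at a fold of at least 4 (percentile 18.3). Setd2 itself held 5 of the 21 control peaks without a Dox peak, and the list was not ranked without Setd2. The demethylase genes Kdm2b (4 of 8 peaks) and Kdm2a (3 of 7) held further ones, and the reader gene Psip1 held 2 of 5. Highest control folds were 24.6 at Psip1, 24 at Kdm2b, 23.4 at Nsd3 and 18.5 at Kdm2a. Phf19 was found in control only (17.2), and Setmar (6.51) and Kdm4c (2.24) in Dox only. Of the 97 Dox peaks 28.9% lacked a control peak, at percentile 67.5.

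Polycomb, DNA methylation and other chromatin regulators had peaks in both conditions in 33 of 35 members. Of 164 control peaks 9.76% (5.68% to 15.4%) and of 171 Dox peaks 21.1% (15.2% to 27.9%) lacked a counterpart, at percentiles 5.80 and 5.10. At a fold of at least 4 the Dox share was 13.6%, at percentile 0.91. At a log10 FDR of -5 or less the control share was 18.2% (percentile 80.6) and the Dox share 19.8% (percentile 46.6). All control peaks of Arid1a (7 peaks, highest fold 30.1), Chd4 (10, 24.6), Ehmt2 (6, 23.4) and Pcgf6 (1, 23.0) overlapped Dox peaks. Rnf2 (2.44) and Ezh1 (2.06), which encode Polycomb enzymes, had peaks in Dox only. Genes of the LIF, MAPK and WNT pathways, which the culture medium acts on, had 27 members with peaks in both conditions, 3 in control only and 3 in Dox only. Their shares without a counterpart, 18.4% of 87 control and 32.3% of 96 Dox peaks, lay at percentiles 62.2 and 73.4. Lif (29.5), Ctnnb1 (27.1), Stat3 (27.1) and Gsk3b (24.8) led the control list. Lef1 (14.8) and Spry4 (13.5) were among those found in control only, and Dusp4 (20.6), Jak2 (7.23) and Tcf7l2 (6.51) in Dox only.

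Cell cycle genes had 24 members with peaks in both conditions and 2 in control only, Rb1 (4.61) and Ccnb2 (4.04). Of their 64 control peaks 12.5% and of their 73 Dox peaks 31.5% lacked a counterpart, at percentiles 19.1 and 57.8. The proliferation marker Mki67 had 12 control peaks, all with a counterpart, and 13 Dox peaks, 4 of them without. Cdk6 (17.2), Mki67 (16), Wee1 (14.3) and Ccnd1 (13.2) had the highest control folds. Apoptosis and p53 pathway genes had 14 members with peaks in both conditions. Only 1 of their 30 control peaks (3.33%, 0.0844% to 17.2%) lacked a Dox peak, at percentile 0.905 with matching on fold and 9.66 with matching on log10 FDR. The share was 11.1% at a log10 FDR of -5 or less (percentile 14.4) and 33.3% at a fold of at least 4 (percentile 14.7). Of 32 Dox peaks 12.5% lacked a control peak, at percentile 2.60 and at 9.67 with matching on log10 FDR, but outside the bounds under both filters, with 4.17% of peaks at a log10 FDR of -5 or less (percentile 2.13) and 0 of those with a fold of at least 4 (percentile 0.885). Phlda3 (46.1), Mcl1 (22.3), Casp9 (18.5) and Bbc3 (17.4) led, and all of their control peaks had a counterpart.

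Ribosomal protein genes had 21 members with peaks in both conditions, and Rpl23 (2.42) in Dox only. Their control peaks, led by Rps14 (9.34), Rps19 (6.81), Rpl7 (6.71) and Rpl4 (6.26), lacked a counterpart in 17.9% of 39 cases, at percentile 43.8 with matching on fold and 99.2 with matching on log10 FDR. Of their 39 Dox peaks 15.4% lacked one, at percentiles 0.345 and 69.0. This call stayed at a log10 FDR of -5 or less (11.1% of 36 Dox peaks, percentile 0.11) and was lost at a fold of at least 4, where 1 of only 3 Dox peaks lacked a counterpart (percentile 58.0) and 84.6% of 13 control peaks did (percentile 98.1). KRAB zinc finger and 2-cell-stage genes had 4 members with peaks in both conditions. Of their 19 Dox peaks 11 had no control peak (57.9%, 33.5% to 79.7%), at percentile 99.5 with matching on fold and 99.2 with matching on log10 FDR. This call was lost under both filters: 25% of 8 peaks at a log10 FDR of -5 or less (percentile 70.7) and 50% of 6 peaks at a fold of at least 4 (percentile 82.3). Zfp57, which maintains genomic imprints, held 3 of these 11 among its 5 Dox peaks, and Zfp568 (2 of 4), Zfp809 (2 of 3) and Zfp961 (1 of 4) held further ones. Zfp808 (5.15) and Zfp459 (2.89) were found in Dox only and Usp17la (40.6) in control only. Of this list's 11 control peaks 27.3% lacked a counterpart, at percentile 74.4.

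Markers of fibroblasts, listed as a check on other cell types although these cultures held no feeder cells per the labels, were found for 6 of 20 genes, 5 of them in both conditions. Of 26 control peaks 23.1% and of 23 Dox peaks 13.0% lacked a counterpart, at percentiles 78.8 and 3.71. Col5a1 (27.1), Col1a1 (24.6), Sparc (11.1) and Vim (8.73) had the highest control folds, and Pdgfrb (17.2) was found in control only.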

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

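No paired analysis was possible because each condition has 1 pooled list without values per library, which also rules out leaving out a replicate. The alternatives fixed beforehand for transcript regions and for the m6A motif were not run, since neither result was computed. All alternatives for peak positions were chosen after the data were seen. With strand ignored or genomic spans, no share moved beyond its interval. The cause of the other shifts was not tested, except that filters and smaller windows leave fewer peaks by construction. Sequencing depth, which is unknown, limits how many weak peaks either list can hold.

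Dox minus control peaks, 1797 in the full tables, reversed to -879 at a log10 FDR of -5 or less, -3534 at a fold of at least 4 and -1414 in the authors' shorter lists. Control and Dox peaks then numbered 16596 and 15717, 14928 and 11394, and 16914 and 15500. Control peaks without a Dox peak were 21.0%, 45.7% and 24% under these filters, and Dox peaks without a control peak 22.3%, 31.6% and 22.3%, so that the excess on the Dox side in the full tables (29.1% against 19.3%) turned at a fold of 4 and in the shorter lists. Overlap of at least 50% of the shorter peak gave 20.9% and 30.5%, equal numbers of peaks 21.5% and 26.6%, and the filter at a log10 FDR of -5 on the query list alone 7.56% and 11.6%. Genes in control only numbered 2841 at a fold of 4 (Dox only 1222), and genes in Dox only 949 at a log10 FDR of -5 (control only 1257). With at least 2 peaks required they numbered 133 and 290.

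Control 5' end peaks kept a higher share without a Dox peak than peaks between the ends under all 9 alternatives. That share was 44.4% at a log10 FDR of -5, 64.2% at a fold of 4, 46.9% in the shorter lists, 21.2% with the filter on control peaks alone and 41.3% in a window of 200 nt. The gap to peaks between the ends, 22.2 percentage points in the full tables, was 26.6 at a log10 FDR of -5, 26.7 in the shorter lists and 15.7 with the filter on control peaks alone. Control and Dox 5' end peaks numbered 1765 and 912 at a log10 FDR of -5, 1903 and 940 in the shorter lists, and 1566 and 937 in the 200 nt window, and Dox ones 865 at a fold of 4. Dox minus control peaks beyond the 5' end, 2762 in the full tables, were 235 at a log10 FDR of -5 and reversed to -1505 at a fold of 4 and -90 in the shorter lists.

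Of the 22 gene list shares, 9 at a fold of 4 and 17 at a log10 FDR of -5 stayed within their intervals, as did all 22 under the other overlap rules. At a fold of 4 the control shares were 31.4% for pluripotency, 33.3% for m6A, 31.7% for H3K36, 41.4% for chromatin, 50% for LIF, MAPK and WNT, 51.9% for cell cycle, 33.3% for apoptosis, 84.6% for ribosomal protein and 53.3% for fibroblast genes. Dox shares there were 13.6% for chromatin, 33.3% for ribosomal protein, and 0 for apoptosis and fibroblast genes. At a log10 FDR of -5 Dox shares were 19.0% for germ layer, 11.6% for m6A, 14.3% for H3K36 and 25% for KRAB genes, and the control share was 18.2% for chromatin genes. The pluripotency control share lay at percentile 1.95 at that FDR and at 7.82 at a fold of 4. The 20 genes named for peaks in a single condition were chosen by limits that these filters do not exceed for their top peaks, so the filters do not test them.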

Other observations

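The tests on windows with few input reads, on pull-down and on the strength of 5' end peaks were chosen after the results they bear on were seen.

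Fewer genes of the m6A machinery had a 5' end peak in Dox (5) than in control (10), as over all genes (1793 and 2791). Those with a control peak within 500 nt of the 5' end were Mettl14, Zc3h13, Rbm15b, Fto, Ythdf2, Ythdf3, Ythdc1, Igf2bp1, Igf2bp2 and Hnrnpa2b1. In Dox the last 3 and the reader genes Ythdf2 and Ythdc1 had one, 5 in all. The remaining genes had Dox peaks centred elsewhere only. At Ythdf3 the 5' end peak (16183212 to 16183512 on chromosome 3) was the control peak of highest fold, 10.1 with a log10 FDR of -34.7, and had no counterpart. 5' end peaks numbered 16 and 10 among Polycomb and other chromatin regulators, 14 and 12 among pluripotency regulators, 13 and 8 among LIF, MAPK and WNT pathway genes and 9 and 8 among cell cycle genes, control first. Apoptosis and ribosomal protein genes had 7 and 4 each, H3K36 genes 6 and 4, fibroblast markers 4 and 2, KRAB genes 1 and 1, and germ layer regulators, the only list with more in Dox, 3 and 5. The counts are small, and none of these differences was tested. They go by peak midpoints, so a wider Dox peak can lower them without loss of a peak.

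Control peaks near gene 5' ends had no Dox peak more often than peaks between the ends. A lower transcript level of the affected genes was tested in the 1877 genes with both kinds of control peak. There 39.1% of 5' end peaks and 11.9% of peaks between the ends lacked a Dox peak. The gap was 27.2 percentage points, where 5 or fewer were predicted, so an equal loss of all peaks of a gene does not describe it. The comparison did not match peaks on log10 FDR, and weakly supported peaks were lost more often. It therefore cannot exclude a lower transcript level. Weaker evidence for 5' end peaks is not enough by itself. Averaged over 6 bands of log10 FDR, the gap was 20.8 points, close to the 22.2 without bands. Less coverage of transcript 5' ends in the Dox libraries, from RNA fragmentation or library preparation, stays open. Of control peaks centred in the first 100 nt 50.4% lacked a Dox peak, and of those at 300 to 500 nt 35.6%, 14.7 points less. The fall was not steady, with 38.2% at 100 to 200 nt, 33.4% at 200 to 300 nt and 31.9% at 500 to 1000 nt. All of these shares lay above the 16.1% of control peaks between the ends. Without coverage of the input libraries, lower 5' coverage cannot be told apart from a change of methylation near transcript starts. An effect of Setd2 knockdown, or of Dox itself, on m6A near transcript starts may therefore be one explanation and was not tested. Coverage of the 4 input libraries over the first 500 nt would show whether 5' coverage fell in Dox, but would not by itself show a change of methylation.

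Peaks of high fold were fewer in the Dox list, although the list was longer. Windows with almost no input reads, as far as folds on whole multiples of a step mark them, are not enough. Some folds of 8 to 40 are not whole multiples of their list's step, nor of that step divided by 2 or 3. Of these the control list held 2393 and the Dox list 414, a ratio of 0.173 (0.156 to 0.192). Over all folds of 8 to 40 the numbers were 6777 and 2593, and over all peaks of fold 8 or more the ratio was 0.375. The intervals of ratios in this paragraph are approximate, cover counting error only and take peaks as independent. A different scaling of IP against input was tested by multiplying the Dox folds by 1.13, the ratio of the steps of 1.23 and 1.0845. This raised the ratio of peak numbers only to 0.484 (0.465 to 0.505), where at least 0.8 was predicted. As far as the steps measure scaling, it is thus not the whole cause. A less efficient pull-down in the Dox libraries, an effect of Dox itself and a lower m6A level after Setd2 knockdown cannot be told apart. Each may lower folds away from gene ends (ratio 0.403), and each condition has 1 pooled list. The ratio was 0.466 at 3' ends and 0.226 at 5' ends, while 1 common factor on control folds that gives the in-between ratio gives 0.344 and 0.541. An equal loss at all positions thus does not describe the counts at 5' ends, which go by peak midpoints.

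Pluripotency genes retained more of their control peaks than random lists matched on fold. Stronger peaks in these genes may be enough to explain this: with random lists matched on the lowest log10 FDR of each gene, a test set before its result was seen, the random median was 10.8% (5.10% to 17.8%) and the list's 6.25% lay at percentile 6.44. A special protection of pluripotency transcripts is thus not needed, though it is not excluded by these lists.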
